A study of Sus scrofa with 6 samples.

How the data were processed

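PolyA RNA from skeletal muscle of Landrace x Pietrain crossbred pigs was sequenced. Per the labels, all animals came from 1 slaughter batch and were slaughtered at 26 weeks of age. There were 12 pigs in each of 3 male categories: entire males (EM), males surgically castrated in week 1 of life (SC), and immunocastrated males (IC), which received a vaccine against gonadotropin-releasing hormone at weeks 12 and 21. Tissue was taken 45 min after death from the right side of the carcass. One sampled muscle was the m. longissimus dorsi (LD), a loin muscle, at the last rib. The other was the m. semispinalis capitis (SSC), a neck muscle, sampled in its biventer cervicis part at cervical vertebra 4. RNA of 6 of the 12 pigs was combined in equal quantity for each category and muscle, so there were 6 libraries, 1 per category and muscle. Whether the LD and SSC pools of a category held the same 6 pigs is not given in the sources used here.

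The deposited table used here holds raw read counts per Ensembl gene, as whole numbers, for 25322 genes and 6 libraries. Per the submitters' processing notes, Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and edgeR (no version given) were used with genome build Sscrofa10.2. The role and order of these programs, the strand setting of the counting and the annotation release are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart, and counts of near-identical paralogs are uncertain. A second deposited table, of FPKM values, was not used: 47.3% of its 151932 values (71797) carry several points within 1 number, so the place of the decimal point is lost. Gene symbols came from a table of Ensembl identifiers, with MYLPF read as MYL11 and DDX58 as RIGI. A RefSeq gene table of Sscrofa11.1, a different build, was used for neighbouring genes alone. A symbol was found for 11804 of the 25322 identifiers and for 9236 of the 14102 genes tested (65.5%). MYH7, MYH2, MYH1, MYH4, LEP and ADIPOQ were not among the tested genes under a symbol.

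Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with filterByExpr grouped by muscle at a minimum count of 10, and libraries were scaled with TMM (trimmed mean of M values) factors. A quasi-likelihood model with category and muscle as additive terms was fitted to all 6 libraries, which left 2 residual degrees of freedom. The common biological coefficient of variation was 0.108 and the prior degrees of freedom were 6.97. The contrasts were SSC over LD, SC over EM, IC over EM, IC over SC, and the mean of SC and IC over EM. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Tests were two-sided. Because there was 1 library per category and muscle, no group had a replicate, the interaction of category and muscle could not be tested (it would leave no residual degrees of freedom), and folds within 1 muscle are given as values. The spread that the tests use is the disagreement between muscles or categories in this additive model, so their p-values do not measure the spread between animals. CPM values are counts scaled to a common library total with the TMM factors, and log2 folds within 1 muscle used a prior count of 2. At the depth of these libraries, 3 counts correspond to 0.0824 to 0.122 CPM in a library. Ratios of summed counts are scaled by the TMM-adjusted library totals. Counting intervals are 95% intervals and cover counting error only. A ± after the median of a list is a standard error over its member genes. Genes are not independent replicates, so it does not measure the spread between libraries or animals.

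Gene lists, tests, the rule for naming genes and the alternatives were fixed before the data were examined. The 31 lists were slow fibre genes, fast fibre genes, glycolysis and glycogen use, nuclear genes of oxidative phosphorylation, the tricarboxylic acid cycle, mitochondrially encoded genes, fatty acid uptake and oxidation, lipogenesis, cholesterol synthesis, adipocyte markers, fibroblast and extracellular matrix genes, basement membrane and endothelial markers, leukocyte markers, erythroid markers, Schwann cell and nerve markers, smooth muscle and pericyte markers, satellite cell and myogenic regulators, neuromuscular junction genes, the growth factor axis, sex steroid receptors with androgen-responsive genes, proteolysis and autophagy, heat shock genes, immediate early genes, circadian clock genes, HOX paralogue groups 1 to 6 with MEIS, HOX paralogue groups 7 to 13, other patterning factors, the cell cycle, the interferon response, MHC class II, and cytosolic ribosomal proteins. The 29 lists with at least 4 tested members were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. For each list, the number of changed members is also given after adjustment over the list alone. The percentile of a list's median within 1 muscle was taken among 10000 random lists of the same size matched on mean expression, as a description of these libraries.

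The rule for named genes in the muscle comparison took genes with a symbol, an adjusted p under 0.05, a mean of at least 10 CPM and the same sign in all 3 categories: the 8 with the largest fold in each direction, and the 4 most abundant in each direction among those with an absolute log2 fold of at least 1. In each category comparison it took the 5 largest folds in each direction among called genes with a symbol, a mean of at least 2 CPM and the same sign in both muscles. Places left over were filled with the largest folds of at least 1 in absolute log2 value among genes that did not pass. Up to 4 members with the smallest p were taken from each list. ESR1, SCD, FASN and IGF1 were named wherever tested. Some genes that the rule would name are not reported here. Other genes named were chosen after their values were seen. They are the remaining called genes with a symbol in the category comparisons, some called genes without a symbol, and several further list members.

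The procedure was tested on simulated counts with 200 changed genes. For SSC over LD it recovered 59% of them at a 1.5-fold, 88% at a 2-fold and 96.5% at a 4-fold change among 13949, 13951 and 13942 genes run. For SC over EM it recovered 39.5%, 77.5% and 98.5% among 13972, 13954 and 13957 genes run, and between 3 and 14 unchanged genes were called per run. The camera step called the 1 changed list and 0 of 20 unchanged lists in simulated data. The simulated genes were independent, so this does not show how often camera falsely calls lists whose genes move together. In these data the estimated correlation was 0.836 for the oxidative phosphorylation list. Alternatives were RLE (median-of-ratios) and upper-quartile factors, library size without a composition factor, no filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, the legacy quasi-likelihood of edgeR, exclusion of mitochondrially encoded genes, an added fold limit, omission of each library in turn, and models without the category or the muscle term. Where leaving out a library left a category with 1 library, that library was assumed to vary like the other groups.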

Results

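Gene expression was measured by RNA sequencing of pooled polyA RNA in 2 muscles of pigs from 3 male categories, to ask how male category affects expression in a loin muscle, m. longissimus dorsi (LD), and a neck muscle, m. semispinalis capitis (SSC). The categories were entire males (EM), surgically castrated males (SC) and immunocastrated males (IC). Each of the 6 libraries pooled 6 animals, with 1 library per category and muscle and no replicate within a group. Total counts were 25588874 in the EM LD library, 25372051 in EM SSC, 36412541 in SC LD, 25082821 in SC SSC, 24544898 in IC LD and 35000845 in IC SSC. Between 16867 and 17679 genes had at least 1 count in a library, and 14102 genes were tested. The 10 most abundant genes held 26.7% ± 0.53 (SD, n = 3 libraries) of the counts in LD and 24.5% ± 0.53 in SSC. Mitochondrially encoded genes held 8.57% ± 1.30 of the counts in LD and 16.0% ± 0.99 in SSC. Muscle separated the libraries along the dimension that carried 70.8% of the variance, with 10.3% on the next. Across genes, which are not independent replicates, Pearson's r of log2 CPM lay between 0.985 and 0.990 for libraries of the same muscle and between 0.953 and 0.961 for libraries of different muscles.

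The comparison of the 2 muscles asked how the neck muscle differs from the loin muscle when category is taken into account, with 3 libraries per muscle. SSC had more RNA for slow-fibre contractile proteins and LD more for fast-fibre proteins. Of the 8 slow fibre genes measured, 7 rose in SSC and 1 fell, with a median log2 fold of 1.90. Among those that rose were the slow troponins TNNI1 (log2 fold 2.11 ± 0.13, SE), TNNT1 (2.07 ± 0.14, from 1763 to 7356 CPM) and TNNC1 (1.97 ± 0.13), and the slow myosin MYH7B (2.49 ± 0.13). The member that fell was SLN (-1.96 ± 0.12), which encodes sarcolipin, an inhibitor of the sarcoplasmic reticulum calcium pump. All 9 fast fibre genes fell in SSC, with a median of -1.71, among them TPM1 (-2.60 ± 0.16), MYBPC2 (-2.26 ± 0.13), ATP2A1 (-1.84 ± 0.14), the calcium pump of fast fibres, and MYL11 (-1.55 ± 0.16, from 22580 to 7728 CPM), the fast regulatory light chain. The list test called both (camera adjusted p = 0.000127 for slow and 2.61e-07 for fast). Neither call held with an estimated correlation (adjusted p = 0.566 and 0.396), a form of the test that can hardly pass here. Both held with fry (adjusted p = 0.0453 for slow and 0.00207 for fast). Counts adjusted over the list alone were the same for both lists. MYH6 rose (1.43 ± 0.13) and MYH13 fell (-3.30 ± 0.11), but the MYH genes are near-identical paralogs and MYH7, MYH2, MYH1 and MYH4 carried no symbol in the old build, so the identity of the MYH transcripts is uncertain.

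Glycolytic genes were lower and genes of mitochondrial oxidation higher in SSC. Of 15 genes of glycolysis and glycogen use, 14 fell (median -2.25, camera adjusted p = 1.02e-12, adjusted p = 0.396 with an estimated correlation), for example the glycogen phosphorylase PYGM (-2.44 ± 0.16), PFKM (-2.47 ± 0.11), PGK1 (-2.43 ± 0.10) and the muscle enolase ENO3 (-1.88 ± 0.17, from 24489 to 6660 CPM). The member that rose was SLC2A4, the insulin-responsive glucose transporter (0.50 ± 0.17). PFKFB3, whose enzyme makes the glycolytic activator fructose 2,6-bisphosphate, fell by 4.56 ± 0.16 on the log2 scale. Of 20 nuclear genes of oxidative phosphorylation, 18 rose and none fell (median 0.53, camera adjusted p = 2.35e-08, adjusted p = 0.566 with an estimated correlation), led by NDUFA4 (1.03 ± 0.13), ATP5MC1 (0.80 ± 0.10) and ATP5F1A (0.79 ± 0.10). In the tricarboxylic acid cycle 8 of 13 genes rose, such as MDH1 (1.41 ± 0.14), and 2 fell, IDH3G (-0.50 ± 0.08) and OGDH (-0.31 ± 0.09), with a median of 0.36 (camera adjusted p = 0.0163, adjusted p = 0.618 with an estimated correlation). Of 13 mitochondrially encoded genes, 6 rose, such as COX1 (0.81 ± 0.22), and none fell (median 0.49, camera adjusted p = 0.00600, adjusted p = 0.618 with an estimated correlation). Fatty acid uptake and oxidation rose in 17 of 21 genes (median 0.79, camera adjusted p = 1.64e-09, adjusted p = 0.396 with an estimated correlation), including the regulators PPARGC1A (2.32 ± 0.12) and PPARA (2.04 ± 0.10) and the enzyme genes HADHB (1.61 ± 0.08) and ACADL (1.57 ± 0.09), while the uncoupling protein gene UCP3 fell (-2.05 ± 0.20). Adjusted over the list alone, 19 genes of oxidative phosphorylation, 7 mitochondrially encoded genes and 18 of fatty acid oxidation rose, and the glycolysis and tricarboxylic acid counts were the same. ESRRG (3.56 ± 0.17) and ESRRB (2.95 ± 0.13), orphan nuclear receptors of oxidative metabolism, and PLIN5 (3.83 ± 0.22), a lipid droplet protein of oxidative tissue, were among the 8 largest rises of genes with a symbol and a mean of at least 10 CPM.

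Lipid genes and markers of cells other than fibres also differed between the muscles. Of 17 lipogenesis genes, 6 rose and 2 fell (median 0.19, camera adjusted p = 0.0162, adjusted p = 0.567 with an estimated correlation). PCK1 (3.39 ± 0.25), MLXIPL (2.40 ± 0.17), GPAM (1.80 ± 0.17) and the stearoyl-CoA desaturase gene SCD (0.78 ± 0.11) rose, ME1 (-0.55 ± 0.10) and INSIG1 (-0.49 ± 0.13) fell, and the fatty acid synthase gene FASN measured 0.03 ± 0.11 (edgeR adjusted p = 0.827). Of 11 adipocyte markers, 9 rose and 2 fell (median 0.98, camera adjusted p = 0.0108, adjusted p = 0.566 with an estimated correlation). PLIN1 (1.71 ± 0.20) and CIDEC (1.30 ± 0.15) rose, while GPD1 (-1.81 ± 0.09), which is also a glycolytic gene, and CFD (-0.38 ± 0.07) fell. Endothelial and basement membrane markers rose in 8 of 11 (median 0.58, camera adjusted p = 0.000269, adjusted p = 0.397 with an estimated correlation), for example KDR (1.17 ± 0.10) and PECAM1 (0.82 ± 0.09). Smooth muscle and pericyte markers rose in 5 of 9 and fell in 1 (median 0.31, camera adjusted p = 0.0203, adjusted p = 0.566 with an estimated correlation), with CSPG4 at 1.09 ± 0.12 and CNN1 at -0.27 ± 0.08. All 3 erythroid genes measured rose, HBB by 1.43 ± 0.10, and none of the 3 Schwann cell genes passed, these lists being too short for a list test. Adjusted over the list alone, 7 lipogenesis genes and 9 endothelial markers rose, and the other counts were the same.

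Of genes with a symbol and a mean of at least 10 CPM, CILP2, COMP, PADI2 and TNMD rose most in SSC. CILP2, a cartilage matrix protein, had 13 counts in the 3 LD libraries and 2379 in the 3 SSC libraries, a ratio of 149.6 after scaling by the TMM-adjusted library totals (counting interval 87.3 to 281). COMP, another cartilage and tendon matrix protein, had 41 and 2487 counts (scaled ratio 49.6, 36.5 to 69.3), and TNMD, a tendon cell protein, 81 and 3293 counts (scaled ratio 33.2, 26.7 to 42.0). The peptidylarginine deiminase gene PADI2 rose by 5.08 ± 0.33 and TECRL by 2.93 ± 0.14. Of the 21 fibroblast and matrix genes, 5 rose, including FMOD (1.46 ± 0.18), TNC (1.23 ± 0.10), THBS4 (1.12 ± 0.11) and POSTN (0.68 ± 0.09), and 1 fell. That list was not called (camera adjusted p = 0.335): its median was -0.03 and its mean 0.19, and the median was 0.01 with upper-quartile scaling and 0.28 with library size only. Counts adjusted over the list alone were the same. Among the largest falls were MYBPH (-7.38 ± 0.22, from 797 to 4.87 CPM), a myosin-binding protein, the adenosine receptor gene ADORA1 (-5.89 ± 0.13), OTUD1 (-4.29 ± 0.52), the amino acid transporter gene SLC7A8 (-3.37 ± 0.12) and EGF (-3.20 ± 0.09). MYBPH and ADORA1 are neighbours in the reference annotation, so shared reads cannot be excluded for ADORA1.

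HOX genes, which encode position along the body axis, separated the muscles. All 4 measured genes of HOX paralogue groups 7 to 13 fell in SSC (median -3.04, camera adjusted p = 8.69e-05, adjusted p = 0.397 with an estimated correlation). HOXC10 had 1015 counts in the LD libraries and 1 in the SSC libraries, a scaled ratio of 1241 (222 to 49073), HOXD9 fell by 3.48 ± 0.12, HOXA7 by 2.60 ± 0.14 and HOXB7 by 1.28 ± 0.21. Of the 12 genes measured of paralogue groups 1 to 6, 8 rose and 4 fell (median 1.22, camera adjusted p = 0.174, not called). HOXB5, with 16 counts in LD and 716 in SSC (scaled ratio 36.6, 22.4 to 64.4), HOXA2 (2.65 ± 0.39), HOXA3 (1.70 ± 0.18) and HOXB3 (1.39 ± 0.16) rose. HOXD1, with 1175 counts in LD and 33 in SSC (scaled ratio of LD to SSC 43.5, 30.8 to 63.6), HOXC6 (-3.79 ± 0.17), HOXD4 (-1.09 ± 0.12) and HOXA5 (-0.88 ± 0.14) fell. Of 14 other patterning factors, 4 rose, including IRX3 (1.97 ± 0.19) and TBX3 (0.94 ± 0.10), and 2 fell, SIM1 (-2.90 ± 0.23) and LBX1, and the list was not called (camera adjusted p = 0.606). Counts adjusted over the list alone were the same for these 3 lists. HOX genes lie in dense clusters with antisense transcripts, and the counting strand is not given, so neighbours may share reads.

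**Figure D1:**
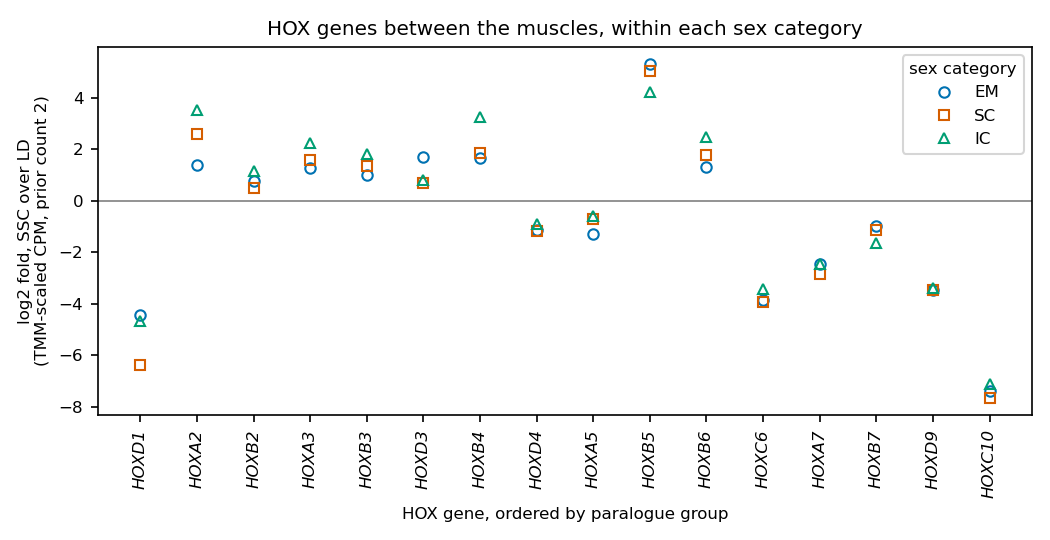
Log2 fold of SSC over LD for each of the 16 measured HOX genes, with 1 point per category. All 4 genes of paralogue groups 7 to 13 were lower in SSC, and 8 of the 12 genes of groups 1 to 6 were higher.

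More genes fell than rose in SSC in the lists of myogenic genes, protein breakdown, immediate early genes and ribosomal proteins. Of 13 satellite cell and myogenic genes, 7 fell, such as MYF6 (from 629.6 to 158.4 CPM), CDH15 (-1.01 ± 0.14) and the uncertain paralogs MYH3 (-1.71 ± 0.10) and MYH8 (-1.51 ± 0.14), and 1 rose, MYOD1 (0.38 ± 0.11), with a median of -0.42 (camera adjusted p = 0.00251, adjusted p = 0.397 with an estimated correlation). Proteolysis and autophagy genes fell in 11 of 17 and rose in 3 (median -0.60, camera adjusted p = 0.00137, adjusted p = 0.566 with an estimated correlation), with ULK1 at -1.33 ± 0.08, FBXO40 at -1.10 ± 0.10 and the lysosomal protease gene CTSL at 1.33 ± 0.16. Immediate early genes, which respond within minutes to stimuli, fell in 10 of 14 (median -1.14, camera adjusted p = 0.000858, adjusted p = 0.605 with an estimated correlation), with ATF3 at -2.95 ± 0.33, FOS at -1.96 ± 0.32, JUNB at -1.18 ± 0.18 and NR4A2 at -1.10 ± 0.13. Cytosolic ribosomal protein genes fell in 11 of 15 and rose in 1 (median -0.35, camera adjusted p = 0.000917, adjusted p = 0.566 with an estimated correlation), led by RPLP1 (-0.98 ± 0.12) and RPS16 (-0.85 ± 0.09), although its medians within EM, SC and IC lay at percentiles 29.98, 19.4 and 21.1 of matched random lists. Interferon response genes rose in 8 of 15 (median 0.39, camera adjusted p = 0.00286, adjusted p = 0.538 with an estimated correlation), for example IFIT1 (0.73 ± 0.14), RSAD2 (0.72 ± 0.12) and IFIT2 (0.66 ± 0.09). Adjusted over the list alone, 12 proteolysis genes, 11 immediate early genes and 12 ribosomal protein genes fell, 10 interferon genes rose, and the myogenic counts were the same. With library size only, the medians were -0.12 for myogenic, -0.29 for proteolysis, -0.83 for immediate early, -0.04 for ribosomal protein and 0.70 for interferon genes.

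The remaining lists were not called between the muscles (camera adjusted p between 0.173 and 0.935). In the growth factor axis 7 of 14 genes fell, among them MSTN (-2.63 ± 0.17), which encodes the growth inhibitor myostatin, and IRS1 (-0.90 ± 0.08), 1 rose, IGFBP4 (0.59 ± 0.08), and IGF1 measured 0.27 ± 0.12 (edgeR adjusted p = 0.106). Among 10 sex steroid receptors and androgen-responsive genes, 3 fell, including ESR1 (-0.57 ± 0.16) and the chaperone gene FKBP5 (-0.62 ± 0.11), and 2 rose, including SRD5A1 (0.55 ± 0.15). ESR1 did not pass with DESeq2 (adjusted p = 0.0903), without the SC LD library (edgeR adjusted p = 0.168) or without the SC SSC library (0.148). Of 13 clock genes 4 rose and 5 fell, the latter including RORA (-1.55 ± 0.11) and CRY2 (-1.04 ± 0.09), of 11 heat shock genes 3 rose and 3 fell, such as HSPB6 (1.74 ± 0.19) and HSPB8 (-1.35 ± 0.13), and of 8 neuromuscular junction genes 2 rose and 3 fell, such as COLQ (2.17 ± 0.40) and MUSK (-1.94 ± 0.16). Cholesterol synthesis genes rose in 5 of 15 and fell in 6, such as FDPS (-0.97 ± 0.09), with a median of 0.05 and a mean of -0.20. Leukocyte markers rose in 4 of 18, such as S100A8 (1.75 ± 0.26), and fell in 2, CSF1R (-0.48 ± 0.12) and ITGAM (-0.53 ± 0.16), 1 of 11 cell cycle genes fell (GADD45B, -0.62 ± 0.14), and 1 of 5 MHC class II genes rose (SLA-DMA, 0.34 ± 0.11). Adjusted over the list alone, 8 growth factor genes, 4 heat shock genes, 6 clock genes and 7 cholesterol genes fell and no MHC class II gene rose, and the other counts were the same. The medians of the neuromuscular junction (-0.28), sex steroid (-0.03), heat shock (-0.10) and clock lists (-0.25) were above 0 with library size only (0.03, 0.28, 0.20 and 0.06), and that of the sex steroid list also with upper-quartile scaling (0.01).

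**Figure D2:**
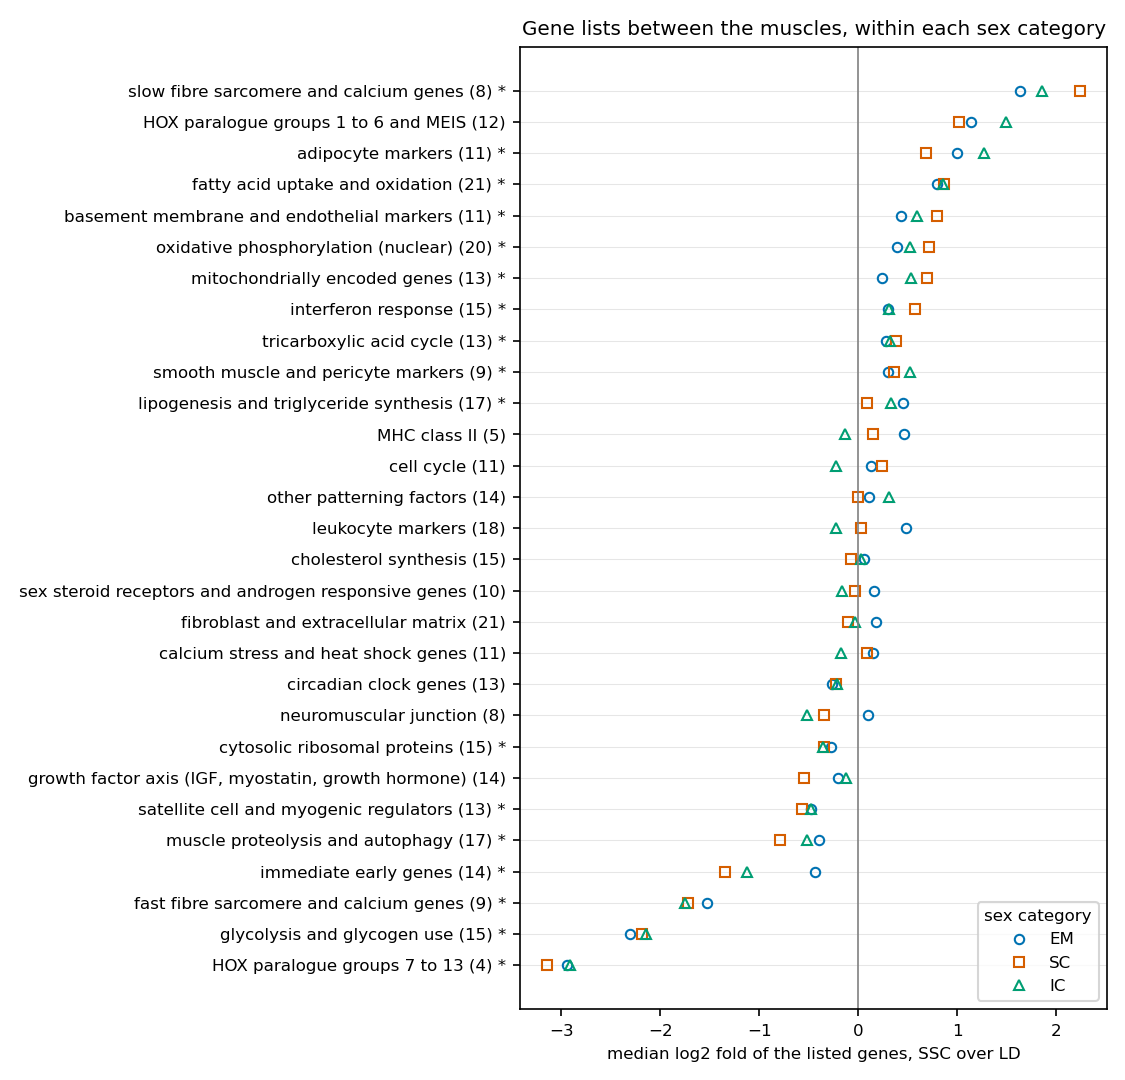
Median log2 fold of SSC over LD for each gene list, with 1 point per category, the number of tested members in brackets and an asterisk where camera with a preset correlation gave an adjusted p under 0.05. Fast fibre (-1.71) and glycolysis (-2.25) lists lay below 0 and slow fibre (1.90) and fatty acid oxidation (0.79) lists above, and 0 lists held with an estimated correlation.

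By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5586 of 14102 genes (39.6%) changed between the muscles: 2721 were higher and 2865 lower in SSC, and 5556 had the same sign in all 3 categories. A change of at least 2-fold was reached by 617 of the higher and 563 of the lower genes. Camera called 17 of 29 lists, 0 of them with an estimated correlation (3 at an unadjusted p under 0.05), and fry 8. Those 8 were fast fibre, glycolysis, myogenic and HOX groups 7 to 13 (fry adjusted p = 0.00207 each), fatty acid oxidation (0.0055), endothelial and ribosomal protein (0.0258 each) and slow fibre genes (0.0453). The other lists that camera called did not pass fry, for example oxidative phosphorylation (0.0623), adipocyte markers (0.0608) and immediate early genes (0.153). The count of changed genes was 3245 without the SC LD library and 3587 without the SC SSC library. Scaling by library size only moved the median of all genes from 0.0045 to 0.31 on the log2 scale and the count to 7480, of which 6227 were higher, so directions are relative to the TMM scaling.

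The comparison of SC with EM asked what surgical castration in the first week of life changed in muscle, with 2 libraries per category, 1 from each muscle. SCD (ENSSSCG00000010554), the desaturase that makes monounsaturated fatty acids, rose in SC by 1.79 ± 0.14 (SE) on the log2 scale, by 1.65 in LD and 1.92 in SSC. PPARGC1A (ENSSSCG00000029275), the coactivator of mitochondrial biogenesis PGC-1 alpha, fell by 1.98 ± 0.15, by 2.23 in LD and 1.77 in SSC. PDK4, the kinase that restrains pyruvate oxidation, fell by 0.97 ± 0.13, from 1932 to 881 CPM in LD and from 2193 to 1242 CPM in SSC. PTX3 (1.10 ± 0.12), which encodes the pattern recognition protein pentraxin 3, and KBTBD12 (0.85 ± 0.11) also rose. The complement gene C7 (-1.54 ± 0.18), ANPEP (-1.12 ± 0.12), which encodes aminopeptidase N, the apolipoprotein gene APOE (-0.90 ± 0.10), PRKAG2 (-0.83 ± 0.10), a subunit gene of AMP-activated protein kinase, and ABHD4 (-0.67 ± 0.09) also fell. Among genes without a symbol, ENSSSCG00000024107 rose (0.89 ± 0.11) and ENSSSCG00000026755 (-1.19 ± 0.11) and ENSSSCG00000023108 (-1.34 ± 0.13) fell. ESR1, IGF1 and FASN did not pass: ESR1 measured -0.46 ± 0.20 (edgeR adjusted p = 0.543), IGF1 -0.60 ± 0.15 (0.244) and FASN 0.79 ± 0.14 (0.115).

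Most genes of the fixed lists did not pass the test between SC and EM, and 5 of 29 lists were called. Of 21 genes of fatty acid uptake and oxidation, 2 fell, PPARGC1A and PDK4, and the list was lower with a median of -0.21 (camera adjusted p = 8.20e-09, adjusted p = 0.791 with an estimated correlation). Nuclear oxidative phosphorylation genes were lower with a median of -0.20 (camera adjusted p = 4.93e-07, adjusted p = 0.791 with an estimated correlation). None of its 20 members passed, the values of NDUFB8 and ATP5MC1 being -0.40 ± 0.10 and -0.38 ± 0.12, and the median was -0.41 within LD and 0.01 within SSC, where mitochondrially encoded genes had medians of -0.37 and 0.13. The EM LD library lay at 0.929 on the dimension that carried 10.3% of the variance, apart from SC LD (-0.251) and IC LD (-0.613). The tricarboxylic acid cycle (median -0.17, camera adjusted p = 0.000207) and the fibroblast and matrix list (median -0.13, camera adjusted p = 0.00088) were also lower, both with an adjusted p = 0.791 with an estimated correlation and no member that passed, for example IDH3B at -0.45 ± 0.10 and COL1A2 at -0.50 ± 0.11. The tricarboxylic acid median was -0.30 within LD and -0.04 within SSC, and the matrix median 0.01 and -0.30. The lipogenesis list was higher (median 0.12, camera adjusted p = 0.0116, adjusted p = 0.791 with an estimated correlation), with SCD as the 1 member of 17 that rose (median of the other 16, 0.09 ± 0.16), while PCK1 measured -1.57 ± 0.29. Adjusted over the list alone, 4 fatty acid oxidation genes, 1 tricarboxylic acid gene and 1 matrix gene fell, none of oxidative phosphorylation did, and 3 lipogenesis genes rose and 1 fell. Adipocyte markers were not called, with a median of -0.01, a mean of 0.06 and PLIN1 at 0.49 ± 0.24, and neither were leukocyte markers, with a median of 0.01 and a mean of -0.03. The 3 Schwann cell genes measured, too few for a list test, had a median of -1.01 and a mean of -0.71, with 1 above 0. Of these, 0 passed over all genes and 1 fell adjusted over the list alone. NR4A3, an immediate early gene, measured -1.56 ± 0.23 (edgeR adjusted p = 0.0655), and the ubiquitin ligase gene TRIM63 measured -1.05 ± 0.22 (0.167).

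By edgeR's quasi-likelihood test, 13 of 14102 genes changed between SC and EM, 4 higher and 9 lower, all with the same sign in both muscles, and 1274 genes had an unadjusted p under 0.05. SCD did not pass without the SC LD library (adjusted p = 0.105), and PDK4 did not without the SC LD (0.377), SC SSC (0.0691) or IC LD library (0.0626). ANPEP was lost without SC LD (0.291) or SC SSC (0.0993), as were C7, APOE, PTX3, KBTBD12, PRKAG2, ABHD4 and the 3 genes without a symbol, and ABHD4 also without IC LD. PDK4 also did not pass with the filter at 1 CPM, ABHD4 with that filter, no filter or library size only, or ENSSSCG00000024107 with no filter. PPARGC1A passed in each of the 6 fits that left out 1 library. The count was 4 without SC LD (1 of the 13 remained), 6 without SC SSC (2 remained), 21 without IC LD, 63 without IC SSC, 88 without EM LD and 671 without EM SSC. It was 66 with DESeq2, 20 with limma-voom and 0 in an edgeR fit without the muscle term (187 at an unadjusted p under 0.05). Without a test, and among genes with a mean of at least 2 CPM, 150 genes differed at least 2-fold within LD and 78 within SSC.

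The comparison of IC with EM asked what vaccination against gonadotropin-releasing hormone changed, again with 2 libraries per category. Interferon-stimulated genes rose in IC: RSAD2, an antiviral enzyme gene, by 1.29 ± 0.15 (SE) on the log2 scale (1.13 in LD and 1.44 in SSC; its neighbour CMPK2 may share reads) and MX1, an antiviral GTPase gene, by 0.94 ± 0.11 (0.96 and 0.92). DNAJB1 (ENSSSCG00000013784), a heat shock co-chaperone gene, rose by 1.03 ± 0.09, from 78.7 to 167.2 CPM in LD and from 94.5 to 185.4 CPM in SSC. SCD rose by 1.01 ± 0.14 (0.73 in LD and 1.27 in SSC). SNCG, which encodes gamma-synuclein, fell by 1.21 ± 0.11 and ANPEP by 0.95 ± 0.12. Of the 6 called genes without a symbol, 3 rose, such as ENSSSCG00000030612 (2.18 ± 0.28, not called with DESeq2 or limma-voom or without SC LD, SC SSC or IC LD), and 3 fell, such as ENSSSCG00000023108 (-1.43 ± 0.13). Genes with large folds that did not pass were NR4A3 (1.43 ± 0.23, edgeR adjusted p = 0.0980), FGF10 (-2.39 ± 0.43, 0.0986), TUBA4A (-1.40 ± 0.28, 0.128) and SLC30A2 (-1.34 ± 0.25, 0.101). PPARGC1A measured -0.00 ± 0.14, ESR1 -0.18 ± 0.20, IGF1 -0.53 ± 0.15 and FASN 0.54 ± 0.14, and none of these passed.

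Between IC and EM 7 of 29 lists were called. The interferon response was higher, with 14 of 15 members above 0 and a median of 0.46 (camera adjusted p = 4.28e-14, adjusted p = 0.709 with an estimated correlation): RSAD2 and MX1 rose over all genes and 10 members rose when adjusted over the list alone, RIGI measured 0.73 ± 0.13 and MX2, a neighbour of MX1 that may share its reads, 0.70 ± 0.13. Immediate early genes were higher, with 14 of 14 above 0 and a median of 0.83 (camera adjusted p = 2.48e-12, adjusted p = 0.709 with an estimated correlation). None of them passed over all genes and 10 rose when adjusted over the list alone, with EGR2 at 1.57 ± 0.35, MYC at 0.85 ± 0.15 and DUSP1 at 0.80 ± 0.18. The immediate early median was 1.30 within LD and 0.52 within SSC. Lipogenesis (median 0.15, camera adjusted p = 0.0109, 1 rose over all genes and 2 adjusted over the list alone) and adipocyte markers (median 0.16, camera adjusted p = 0.0363, 0 rose over all genes and 2 adjusted over the list alone, PLIN1 at 0.90 ± 0.24 and LGALS12 at 1.75 ± 0.40) were higher, both with an adjusted p = 0.709 with an estimated correlation. Within LD the lipogenesis and adipocyte medians were 0.07 and 0.08, at percentiles 83.5 and 82.0 of matched random lists. Within SSC they were 0.17 and 0.15, at percentiles 99.9 and 98.5. Oxidative phosphorylation (median -0.30, camera adjusted p = 3.03e-11) and the tricarboxylic acid cycle (median -0.21, camera adjusted p = 0.000146) were lower, both with an adjusted p = 0.709 with an estimated correlation. None of their members passed over all genes, UQCRC2 measuring -0.46 ± 0.13 and MDH1 -0.49 ± 0.17, and 4 and 1 fell when adjusted over the list alone. The oxidative phosphorylation median was -0.39 within LD and -0.20 within SSC, that of the tricarboxylic acid cycle -0.26 and -0.10 (percentile 11.7 of matched random lists), and that of mitochondrially encoded genes -0.33 and -0.01. The EM LD library of this comparison is the one that lay apart from SC LD and IC LD (0.929 against -0.251 and -0.613). Ribosomal protein genes were lower (median -0.07, camera adjusted p = 0.0363, adjusted p = 0.780 with an estimated correlation), with 0 that passed over all genes or adjusted over the list alone. Leukocyte markers, measured beside the interferon genes, were not called (camera adjusted p = 0.941): their median was 0.06 and their mean -0.02, but the median was 0.29 within LD, where that of the interferon genes was 0.34, and -0.17 within SSC, where that of the interferon genes was 0.57, and S100A8 measured -1.87 ± 0.31. Of 11 heat shock genes, DNAJB1 rose, and the list was not called (camera adjusted p = 0.0776). The 3 Schwann cell genes, too few for a list test, had a median of -1.08 and a mean of -0.70, with 1 above 0. Of these, 0 passed over all genes and 1 fell adjusted over the list alone.

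By edgeR's quasi-likelihood test, 12 genes changed between IC and EM, 7 higher and 5 lower, all with the same sign in both muscles, and 1331 had an unadjusted p under 0.05. Without the SC LD library the adjusted p of RSAD2 was 0.0554, of MX1 0.103, of DNAJB1 0.0524, of SNCG 0.0524, of ANPEP 0.129 and of SCD 0.152. RSAD2 (0.0766), MX1 (0.113) and ANPEP (0.227) also did not pass without IC LD, SCD (0.0592) and ANPEP (0.0511) without SC SSC, or SCD without IC SSC (0.0771). SCD also did not pass with upper-quartile scaling, library size only, no filter or the filter at 1 CPM. The count was 1 without SC LD (0 of the 12 remained), 20 without SC SSC, 23 without IC LD, 51 without IC SSC, 76 without EM LD and 776 without EM SSC. It was 84 with DESeq2 and 0 in an edgeR fit without the muscle term (202 at an unadjusted p under 0.05). Without a test, 201 genes with a mean of at least 2 CPM differed at least 2-fold within LD and 65 within SSC.

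The comparison of IC with SC asked whether the 2 ways of castration differ, with 2 libraries per category. NR4A3 (ENSSSCG00000005385), an orphan nuclear receptor of the immediate early class, was higher in IC by 2.99 ± 0.24 (SE) on the log2 scale, at 136.6 against 25.2 CPM in LD and 240.3 against 19.8 CPM in SSC. PPARGC1A was higher by 1.98 ± 0.15, at 47.9 against 9.64 CPM in LD and 201.3 against 62.5 CPM in SSC. PRKAG2 (1.21 ± 0.10), RSAD2 (1.16 ± 0.15), DNAJB1 (1.10 ± 0.09) and MX1 (0.86 ± 0.11) were also higher, as was ENSSSCG00000002471 (1.02 ± 0.10). SNCG (-1.39 ± 0.11) and SLC4A4 (-0.88 ± 0.11), a sodium bicarbonate cotransporter gene, were lower. SCD measured -0.77 ± 0.13 (edgeR adjusted p = 0.133), FASN -0.25 ± 0.14 (0.813), IGF1 0.08 ± 0.15 (0.974) and ESR1 0.28 ± 0.20 (0.879).

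**Figure D3:**
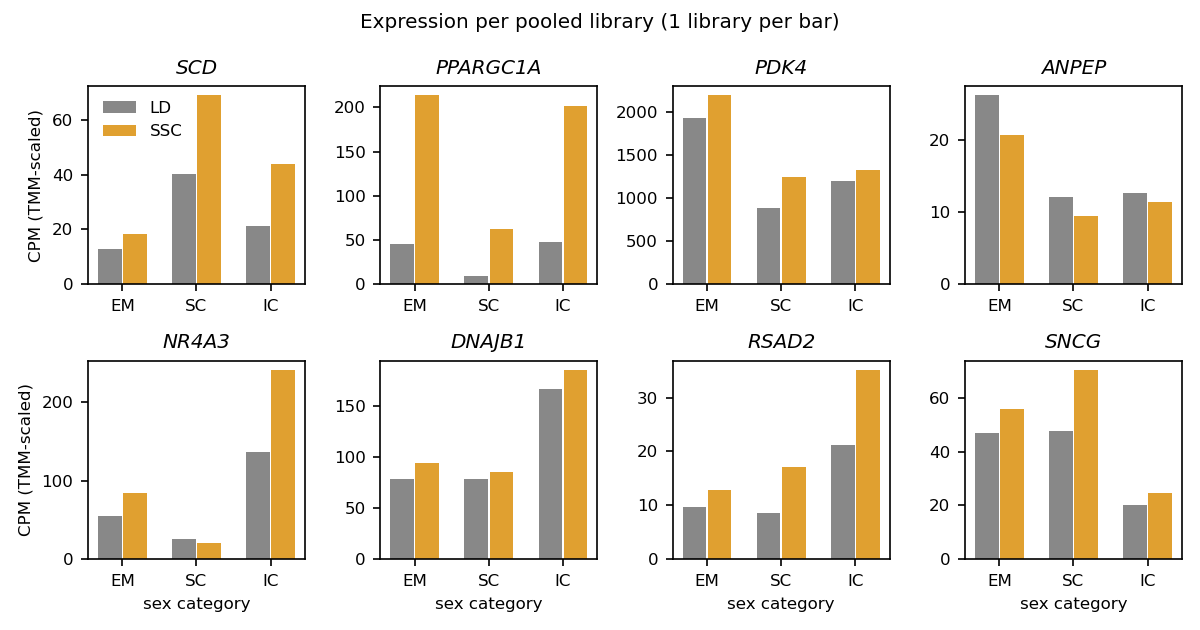
TMM-scaled CPM in each of the 6 libraries for SCD, PPARGC1A, PDK4, ANPEP, NR4A3, DNAJB1, RSAD2 and SNCG, with 1 bar per library. NR4A3 stood at 25.2 and 19.8 CPM in the SC libraries against 136.6 and 240.3 in the IC libraries, and SNCG at 24.5 CPM in the IC SSC library against 70.3 in the SC SSC library.

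All 6 lists called between IC and SC were higher in IC. The interferon response had 14 of 15 members above 0 and a median of 0.55 (camera adjusted p = 7.26e-18, adjusted p = 0.586 with an estimated correlation), with 2 that rose over all genes, RSAD2 and MX1, and 12 adjusted over the list alone, while MX2 measured 0.82 ± 0.13 and OAS2 0.55 ± 0.12. Immediate early genes had 13 of 14 above 0 and a median of 0.69 (camera adjusted p = 6.71e-11, adjusted p = 0.868 with an estimated correlation), with NR4A3 past the test over all genes and 8 adjusted over the list alone, while NR4A2 measured 1.06 ± 0.16 and JUNB 0.80 ± 0.21. Fatty acid uptake and oxidation had a median of 0.12 (camera adjusted p = 2.29e-05, adjusted p = 0.868 with an estimated correlation), with 1 of 21 that rose, PPARGC1A, and 2 adjusted over the list alone. Proteolysis and autophagy had a median of 0.11 (camera adjusted p = 0.0183, adjusted p = 0.888 with an estimated correlation), with 0 past the test and 3 that rose and 1 that fell adjusted over the list alone, FOXO1 at 0.68 ± 0.15 and CTSL at -0.91 ± 0.19. Its median was -0.01 within LD and 0.12 within SSC. Adipocyte markers (median 0.23, camera adjusted p = 0.0405, adjusted p = 0.868 with an estimated correlation) had medians of -0.06 within LD and 0.47 within SSC, with LIPE at 0.51 ± 0.22. Matrix genes (median 0.06, camera adjusted p = 0.0467, adjusted p = 0.966 with an estimated correlation) had medians of -0.02 and 0.17, with TNC at 0.48 ± 0.12. Neither list had a member past the test over all genes or adjusted over the list alone.

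**Figure D4:**
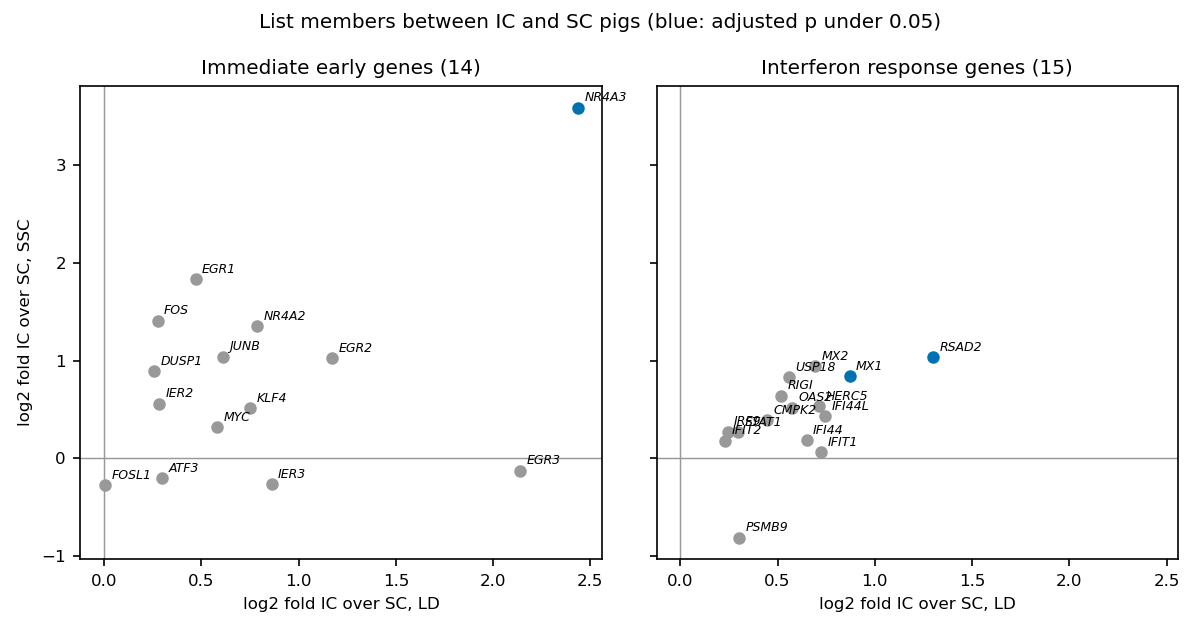
Log2 fold of IC over SC in SSC against that in LD for the 14 immediate early genes and 15 interferon response genes measured, with blue points for genes at an adjusted p under 0.05 (NR4A3, RSAD2 and MX1). NR4A3 lay at 2.44 in LD and 3.59 in SSC.

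By edgeR's quasi-likelihood test, 9 genes changed between IC and SC, 7 higher and 2 lower in IC, all with the same sign in both muscles, and 936 had an unadjusted p under 0.05. NR4A3, PPARGC1A and SNCG passed in each of the 6 fits that left out 1 library. RSAD2 did not pass without SC LD (adjusted p = 0.332), SC SSC (0.0748), IC LD (0.120) or IC SSC (0.0797), and MX1 and SLC4A4 were lost without the same 4 libraries, while PRKAG2 (0.131) and DNAJB1 (0.106) were lost without SC LD, and ENSSSCG00000002471 without SC LD or IC LD. RSAD2, MX1 and SLC4A4 also did not pass with the filter at 1 CPM, where the count was 6. It was 6 without SC LD, 11 without SC SSC, 16 without IC LD, 23 without IC SSC, 189 without EM LD and 381 without EM SSC. It was 44 with DESeq2 and 0 in an edgeR fit without the muscle term (140 at an unadjusted p under 0.05). Without a test, 71 genes with a mean of at least 2 CPM differed at least 2-fold within LD and 84 within SSC.

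The mean of both castrate groups was compared with EM to ask what the loss of testicular function changed whichever way it came about, with 4 castrate libraries and 2 EM libraries. SCD (1.40 ± 0.12, SE) and PTX3 (0.89 ± 0.11) rose, and C7 (-1.28 ± 0.15), ANPEP (-1.03 ± 0.10), PPARGC1A (-0.99 ± 0.12), PDK4 (-0.84 ± 0.11) and APOE (-0.74 ± 0.08) fell on the log2 scale. For PPARGC1A the mean joined -1.98 ± 0.15 in SC with -0.00 ± 0.14 in IC, while ANPEP measured -1.12 ± 0.12 and -0.95 ± 0.12. SCD, ANPEP and ENSSSCG00000023108 were called in both SC over EM and IC over EM, with 1 higher and 2 lower, against a mean of 0 shared calls in 20 simulations in which the contrasts shared nothing but the EM libraries. Those simulations hold no real effects, so the comparison does not separate an effect common to both castrate groups from the shared EM libraries. FASN (0.66 ± 0.12, edgeR adjusted p = 0.106), IGF1 (-0.57 ± 0.12, 0.155) and ESR1 (-0.32 ± 0.17, 0.586) did not pass.

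The called lists of this comparison were oxidative phosphorylation (median -0.23, camera adjusted p = 1.86e-10), the tricarboxylic acid cycle (-0.17, 1.69e-05), fatty acid oxidation (-0.13, 7.67e-06) and matrix genes (-0.09, 0.0110), all lower, and lipogenesis (0.16, 0.00408), immediate early genes (0.54, 1.69e-05) and the interferon response (0.19, 3.16e-06), all higher. With an estimated correlation their adjusted p values lay between 0.824 and 0.826 and 0 of the 29 lists passed (0 at an unadjusted p under 0.05). These means joined unlike values: in SC over EM the interferon (median 0.04, camera adjusted p = 0.965) and immediate early lists (0.22, 0.606) were not called, and in IC over EM the fatty acid (-0.09, 0.0552) and matrix lists (-0.06, 0.205) were not. Over all genes 2 members of the fatty acid list fell, PPARGC1A and PDK4, SCD rose, and no member of the other 5 lists passed. Adjusted over the list alone, 5 oxidative phosphorylation, 1 tricarboxylic acid, 4 fatty acid and 1 matrix gene fell, and 1 fatty acid, 2 lipogenesis, 4 immediate early and 5 interferon genes rose. Within LD the medians of oxidative phosphorylation and the tricarboxylic acid cycle were -0.40 and -0.30, and within SSC -0.10 and -0.06 (percentiles 5.49 and 27.7 of matched random lists). The EM LD library lay apart from the SC and IC libraries of LD on the dimension that carried 10.3% of the variance (0.929 against -0.251 and -0.613). The matrix list had a median of 0.03 within LD, and the immediate early list a median of -0.09 within SSC. MX1 measured 0.51 ± 0.10 and MYC 0.62 ± 0.13, and neither passed. The 3 Schwann cell genes, too few for a list test, had a median of -1.04 with 1 above 0. Of these, 0 passed over all genes and 1 fell adjusted over the list alone.

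By edgeR's quasi-likelihood test, 14 genes changed, 6 higher and 8 lower in the castrates, all with the same sign in both muscles, and 1430 had an unadjusted p under 0.05. The count was 0 without the SC LD library (948 at an unadjusted p under 0.05), where SCD had an adjusted p of 0.0877, ANPEP 0.0906, PPARGC1A 0.0877 and PDK4 0.139, and PDK4 also did not pass without IC LD (0.0870). It was 69 without EM LD, 766 without EM SSC, 21 without SC SSC, 17 without IC LD and 96 without IC SSC. C7 and APOE also did not pass without IC LD, PTX3 without IC LD or SC SSC, or C7 with DESeq2. It was 89 with DESeq2 and 0 in an edgeR fit without the muscle term (225 at an unadjusted p under 0.05).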

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

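The 29 gene lists with a list test were compared between the muscles within each category comparison, and a list is given here where its median had opposite signs in LD and SSC and both medians lay outside the central 95% of matched random lists. This held for 7 of 116 pairs of medians. The pairs are not independent, since castrates over EM is the mean of SC over EM and IC over EM, and IC over SC is their difference. Every comparison with EM in LD also uses the EM LD library, which lay apart from SC LD and IC LD. The differences between the muscles were not tested, since there was 1 library per category and muscle, and no explanation was weighed for them.

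In IC over EM, the 12 tested genes of HOX paralogue groups 1 to 6 (no MEIS gene was tested) had a median log2 fold of -0.38 in LD and 0.35 in SSC. The random lists were matched on mean expression over all 6 libraries. Members with few counts in LD, such as HOXB5 with 16, can therefore vary more there than the random lists. Leukocyte markers had medians of 0.29 in LD and -0.17 in SSC. In SC over EM, immediate early genes had medians of 0.70 in LD and -0.38 in SSC, and mitochondrially encoded genes -0.37 in LD and 0.13 in SSC. In IC over SC, cell cycle genes had medians of 0.32 in LD and -0.28 in SSC. In the mean of the castrates over EM, leukocyte markers had medians of 0.18 in LD and -0.21 in SSC, and mitochondrially encoded genes -0.34 in LD and 0.0850 in SSC.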

How the results depend on the processing

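All alternatives reported in this part were planned. Across the alternatives, 573 values of named genes kept their direction and their side of the threshold, 51 were weaker, 22 stronger and 5 reversed. Of the called category genes with a symbol, PPARGC1A (SC over EM and IC over SC), NR4A3 and SNCG (IC over SC) passed in all 6 fits without 1 library and in all 8 other settings. Between the muscles, 5586 genes changed in the model of the report, and between 4111 (DESeq2) and 7480 (library size only, 6227 higher and 1253 lower against 2721 and 2865) did with other scalings, filters and tools. With an absolute log2 fold of at least 1 the counts were 1180 between the muscles, 7 for SC over EM and 6 for the castrates over EM, fewer by construction. DESeq2 called 66 genes for SC over EM, 84 for IC over EM, 44 for IC over SC and 89 for the castrates over EM, and limma-voom called 20 for SC over EM, and the cause was not tested. Without the muscle term 0 genes were called for SC over EM (187 at an unadjusted p under 0.05), 0 for IC over EM (202), 0 for IC over SC (140) and 0 for the castrates over EM (225), since the difference between the muscles then counts as residual spread. Without 1 library the counts ranged from 3245 to 5966 between the muscles, from 4 to 671 for SC over EM, from 1 to 776 for IC over EM, from 6 to 381 for IC over SC and from 0 to 766 for the castrates over EM, with the highest of each without EM SSC and the lowest without SC LD. The cause was not tested.

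Of the list tests, camera with an estimated correlation called 0 lists in SSC over LD (3 at an unadjusted p under 0.05), 0 in SC over EM (1), 0 in IC over EM (1), 0 in IC over SC (1) and 0 in the castrates over EM (0), against 17, 5, 7, 6 and 7 with the preset correlation. Fry called 8 in SSC over LD, 0 in SC over EM, 0 in IC over EM, 0 in IC over SC and 0 in the castrates over EM (16, 1, 2, 3 and 2 at an unadjusted p under 0.05). With 2 residual degrees of freedom a correlation between genes is poorly estimated, and this form of camera can hardly reach an adjusted p under 0.05. The size of the correlation does not account for every lost call. For the fast fibre list in SSC over LD the estimate was -0.0391, below the preset 0.01. Its camera p was still 0.0291, against 3.60e-08 with the preset. The 0 calls with an estimated correlation therefore decide nothing about a list.

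The 5 reversals were of log2 folds near 0 that did not pass in any fit. Without 1 library the fold of FASN in SSC over LD ranged from -0.0817 (-0.0772 without EM LD) to 0.190. ESR1 ranged from -0.370 to 0.00792 in IC over EM, and IGF1 from -0.0291 to 0.187 in IC over SC (-0.00826 without SC SSC). The cause was not tested. The planned limma-trend fits of log2 FPKM with an offset of 1 or 0.1 were not run, because the FPKM values had lost their decimal points. Depth limited genes with few counts, 3 counts being 0.0824 to 0.122 CPM in a library.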

Other observations

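Across the 11283 genes with enough counts, which are not independent, the log2 folds within LD and within SSC had a Pearson correlation of 0.137 for SC over EM, 0.176 for IC over EM and 0.175 for IC over SC. Crossing the contrasts between muscles gave 0.104 (SC over EM in LD with IC over EM in SSC) and 0.0684 (IC over EM in LD with SC over EM in SSC). Over both muscles, the folds of SC over EM and IC over EM had a correlation of 0.589 across 11344 genes, and the simulated mean was 0.511 with no shared effect in 20 simulations. The covariance was 0.0334 against a simulated 0.0176, a difference of 0.0159. The overlap of 1 higher and 2 lower calls compared with 0 in the simulations and with 0.00199 and 0.00319 for independent lists. The simulations gave each gene the residual spread typical of its expression level, not its own. The covariance difference leaves out what that typical spread adds through the shared EM libraries. Spread of genes beyond it can still be part of the difference. A deviation of the EM pools common to both muscles was not simulated. That deviation can also be part of the difference. For the overlap of calls, the EM libraries were too few to be split, so what they add to real effects was not separated.

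The tests below were set after the most changed genes of each comparison, pooled over the muscles, had been seen, but before the list medians, the folds within a muscle and the splits of the libraries had been. The tests of leukocyte markers within LD and within SSC were chosen after their values were seen. The ± of list medians below is over member genes, not over libraries.

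SCD was higher in SC than in EM by 1.79 ± 0.14. More adipocyte RNA in the SC pools would raise adipocyte markers with it, and their median was -0.00945 ± 0.119. It was 0.07 within LD and -0.07 within SSC, against 1.65 and 1.92 for SCD. This argues against a rise of adipocyte RNA as large as that of SCD in SC over EM. A smaller rise is left open. The list lacks LEP and ADIPOQ and holds GPD1, which is also a glycolytic gene. Of its 11 members 5 lay above 0, PLIN1 among them. A joint rise of lipogenic genes is left open: without SCD, the other 16 members had a median of 0.0918 ± 0.156 (camera p = 0.0296, and p = 0.334 with an estimated correlation). SCD was also called higher in IC than in EM (1.01 ± 0.14), against the same EM libraries and in 3 of the 6 fits without 1 library and 4 of 8 other settings. In IC over EM adipocyte markers were called higher (median 0.16, camera adjusted p = 0.0363, and 0.709 with an estimated correlation). More adipocyte RNA was not tested there for SCD. No biological explanation was tested.

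Interferon response genes were higher in IC than in EM, with a median of 0.46 ± 0.12. More leukocyte RNA in the IC pools would raise leukocyte markers, and their median of 0.0624 ± 0.148 over both muscles decides nothing, since the muscles went opposite ways. Within SSC their median was -0.1697 ± 0.140 against 0.57 ± 0.14 for the interferon genes, which argues against a joint rise of these markers for that pair of libraries. The list mixes markers of several leukocyte types, so a rise of a single type is left open. Within LD it was 0.292 ± 0.187 against 0.34 ± 0.09, which leaves it open. With a single IC library behind it, the interferon median would leave matched random lists in 1 muscle only. It lay at percentile 99.99 within LD and 100 within SSC, so the rise was seen in both muscles. This does not decide about a single library. RSAD2 and MX1 had already passed a fit over both muscles, and random lists hold unrelated genes. In 7 of 116 pairs, list medians left the random lists in opposite directions. With pooled animals, a few pigs with an infection could give the same values in both muscles if the pools held the same pigs, and that was not tested.

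NR4A3 and PPARGC1A were higher in IC than in SC. Their 4 folds within a muscle ranged from 1.69 to 3.59, but both genes had been chosen by a fit over both muscles, so these folds decide nothing about a single library. An acute response around slaughter would move immediate early genes together, and without the NR4A genes the other 12 had a median of 0.60 ± 0.16 (camera p = 1.56e-07, and p = 0.206 with an estimated correlation). In IC over EM, however, PPARGC1A measured -0.00 ± 0.14 beside an immediate early median of 0.83. In SC over EM the muscles differed. Within LD, PPARGC1A (-2.23) and NR4A3 (-1.11) were lower beside an immediate early median of 0.70. Within SSC, PPARGC1A measured -1.77 and NR4A3 went from 84.7 CPM in EM to 19.8 CPM in SC, beside an immediate early median of -0.38. PPARGC1A thus moved with the immediate early genes in IC over SC and in SC over EM within SSC. It did not in IC over EM or in SC over EM within LD, where NR4A3 did not either. For PPARGC1A, the IC pools lay near the EM pools, at 47.9 against 45.4 CPM in LD and 201.3 against 213.4 CPM in SSC. The SC pools lay lower, at 9.64 and 62.5 CPM. Immediate early medians in IC over EM were 1.30 within LD and 0.52 within SSC. These values argue against a response in the IC pools as the source of the PPARGC1A fold. Whether the SC pools responded less is left open for it. For NR4A3 in IC over SC, a response at slaughter is left open.

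For the number of genes changed between the muscles, 1 of the 10 splits of the 6 libraries into 2 groups of 3, the real one, reached 5586, and the highest of the others was 0. Of the 10, 4 parted the libraries of every category as the real one does, and the others put both libraries of a category in 1 group. With so few splits no share under 0.05 can be reached.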
